A study of Arabidopsis thaliana with 24 samples.

How the data were processed

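Gene expression was measured in 10-day-old Arabidopsis thaliana seedlings of the wild type and of kai2-2, a mutant of KAI2, the receptor for karrikins (butenolides found in smoke) and for an unidentified endogenous ligand. Plants of both genotypes were grown in soil in trays at 23 °C and were either kept there or moved to 40 °C for 6 h or 24 h, per the labels' protocols. Each of the 6 groups held 4 biological replicates, per the labels, so 24 arrays were measured with 1 colour (Cy3) on an Agilent Arabidopsis design (021169 in the file headers) that puts 4 arrays on a slide. The labels' tissue field names whole seedlings, whereas the extract protocol names aerial tissues, so the presence of roots in the samples is not settled by the labels. The time of day at which control plants were harvested is not given in the sources used here.

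The deposited scanner output gives each spot's intensity on a linear scale, per the file headers. The column used, the processed signal, is the spot's intensity after background subtraction and detrending within the array by the scanner software, with surrogate values for low signals and no normalization between arrays, per the file headers. The file headers name Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. Probe coordinates are those in the file headers' annotation, which names the TAIR10 build. The authors' value table covers 9999 of the 43603 probes. Set against the scanner values, the deposited table behaved as log2 values of a quantile-normalized median signal, of which the authors appear to have taken the log2 again. No source used here records that step. With the outer logarithm undone, the slope against the scanner values was 0.97 to 0.977 on the log2 scale, with r of 0.9945 to 0.9953. The direction of that table is that of the scanner values, its genes were not centred, and the medians of its columns were 3.281 to 3.295. How the authors chose its probes is not given in the sources used here.

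Control spots and spots with an outlier flag were left out, and spots of a probe were averaged. The log2 of the processed signal had the 75th percentile of its own array subtracted, so every level below is a log2 value relative to that percentile, and a level of 0 equals it. A probe was kept if the scanner software called it well above background on all 4 arrays of at least 1 group, which 33559 probes were. Probes were named by looking up the transcript accessions in the files in a RefSeq gene table of assembly TAIR10.1. The main accession named 34330 probes and another accession 337, and the locus name in the files named 1214. The same table gave the symbols and was used for names only, not for positions. Of the 43603 probes, 35881 were named with 1 gene (82.3%), 12 with several and 7710 with none. Of the 26043 genes with a probe, 20953 were tested, 23 of them with a missing value. A gene's value is that of its probe with the highest mean, and among 6620 genes with several probes 1 to 11 per comparison had probes called in opposite directions.

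On each array, 30167 to 33802 probes were well above background and 0 were saturated, and the 75th percentile of the processed signal was 1913.0 to 2952.2. With 4 arrays per group, the number of arrays limits the precision. Where a gene was not well above background on any array of a group, only a bound was given. The bright group's mean was set against a dim group's mean in which each array took the higher of the gene's own signal and the lowest signal of a probe well above background, and the result is written as "at least N-fold".

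Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in a fit of all 24 arrays with a mean per group and 18 residual degrees of freedom. The 9 comparisons were kai2 against the wild type at the control temperature, after 6 h and after 24 h, each heat time against the control in each genotype, and at each heat time the difference between the heat responses of the genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested together with a change of at least 2-fold. Tables were made and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The fit was tested on simulated data over 20930 genes. Every group had the wild-type control means and the same spread per gene, and 50 genes per size of change were shifted in the wild-type 6 h group. In the comparison of that group with the control, the fit recovered 82.0% of genes changed by a log2 of 1.2, 84.0% at 1.5, 94.0% at 2 and 96.0% at 3, and called 3 unchanged genes. The simulation held no unequal spread of groups and no slide effects, so it does not test those.

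Gene lists of 431 members were fixed for 22 groups, of which 420 had a probe and 400 were tested. The groups are heat shock proteins, heat shock factors, the unfolded protein response, karrikin and strigolactone signalling, scavenging of reactive oxygen species, cutin and wax, abscisic acid, phenylpropanoids and anthocyanins, photosynthesis, warm-temperature growth and auxin, the cell cycle, glucosinolates, salicylic acid and immunity, jasmonate, senescence, raffinose sugars and proline, the circadian clock, autophagy, root markers, seed markers, reference genes and ONSEN retrotransposons. The 8 ONSEN loci had 0 probes, so 21 lists were tested. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of 189 such tests, 59 passed, and with a correlation estimated from the residuals 0 of these held, so both adjusted p-values are printed. Counts of called members adjusted over the list alone were the same as those over all genes tested in 181 of the 189 cases, and the other 8 counts are given with their lists.

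The lists, the tests and the rule for naming genes were written before the data were examined. The rule took KAI2, the 6 largest increases and 6 largest decreases among called genes whose groups did not overlap (without that condition for differences of responses), and from each list up to 4 called members, or 2 members as values where fewer than 2 were called. The ranking of the largest changes was then narrowed to genes well above background on all 4 arrays of every group compared, because fitted values of dim genes have no order. Genes named because few members of a list moved in a direction, and those said to be shared by comparisons, fall outside the rule and were chosen after their values were seen. AT3G24420 and KUF1 are members of the karrikin list.

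Each group lay on a slide of its own, so slide and group cannot be told apart, and p-values measure the spread between arrays within slides. The slides were scanned on 3 days: both 6 h groups on a day, both control groups on another and both 24 h groups on the remaining day, so each comparison of genotypes lies within a scan day and each comparison of heat with control runs across scan days. Scan day and heat time cannot be told apart. Alternatives tried were other scalings and background corrections, the authors' value table, other filters, probe rules, sample sets, variance models, array weights and thresholds, a replicate block, and leaving out each replicate. A slide block was not run, because each slide holds 1 group. Leaving out wild-type control arrays 3 and 4, or 1 and 2, and restricting the scanner values to the genes of the authors' table were chosen after seeing the data. Chromosome positions are given only as the files state them, and no reference genome was used here.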

Results

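Transcript levels of 20953 genes were compared in seedlings of the wild type and of the kai2-2 mutant (kai2) grown at 23 °C or exposed to 40 °C for 6 h or 24 h. The study asked which transcriptional differences accompany the regulation of heat tolerance by KAI2. Each of the 6 groups held 4 arrays, so n = 4 for every group mean below. Levels are log2 values relative to the 75th percentile of each array, changes are differences of group means on the log2 scale, and a value after ± is a standard error unless it is called an SD.

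KAI2 transcript (AT4G37470, read by a probe at chromosome 4, 17617089 to 17617148) was well above background on all 24 arrays. Its mean level was 3.40 in the wild type and 3.59 in kai2 at 23 °C, a difference of 0.19 ± 0.09 (adjusted p = 0.0653). After 6 h it was 2.87 in both genotypes, and after 24 h it was 1.52 in the wild type and 2.05 in kai2, a difference of 0.52 ± 0.09 that lay under 2-fold (adjusted p = 6.76e-05). Where this probe lies relative to the kai2-2 lesion was not analysed here, so the KAI2 level does not check the genotype labels. A pair of genes known as transcriptional markers of karrikin signalling separated the genotypes on every array. AT3G24420 (DLK2, an alpha/beta-hydrolase related to KAI2; chromosome 3, 8863303 to 8863362) was lower in kai2 by log2 changes of -7.61 ± 0.67, -7.67 ± 0.67 and -6.98 ± 0.67 at 0, 6 and 24 h of heat (highest adjusted p = 1.25e-07). At 6 h it was well above background on 2 of the 4 kai2 arrays, and without kai2 array 4, at -4.05 against -9.15 to -8.00 on the others, the difference was -8.80. KUF1 (KARRIKIN-UP-REGULATED F-BOX 1; chromosome 1, 11221551 to 11221610) was lower by -2.80 ± 0.20, -3.47 ± 0.20 and -2.74 ± 0.20 (highest adjusted p = 3.05e-09). In the karrikin and strigolactone list of 18 measured genes, 2 were higher and 4 lower at 23 °C (camera adjusted p = 0.229). After 6 h, 2 were higher and 4 lower (camera adjusted p = 0.0259, adjusted p = 0.33 with an estimated correlation, and 0.112 with only the groups compared in the fit), and after 24 h, 1 was higher and 3 lower (camera adjusted p = 0.0298, adjusted p = 0.733 with an estimated correlation, 0.0907 with only the groups compared in the fit, and 0.0608 with signal on all 24 arrays). The genes lower at all 3 times were AT3G24420 and KUF1.

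**Figure D1:**
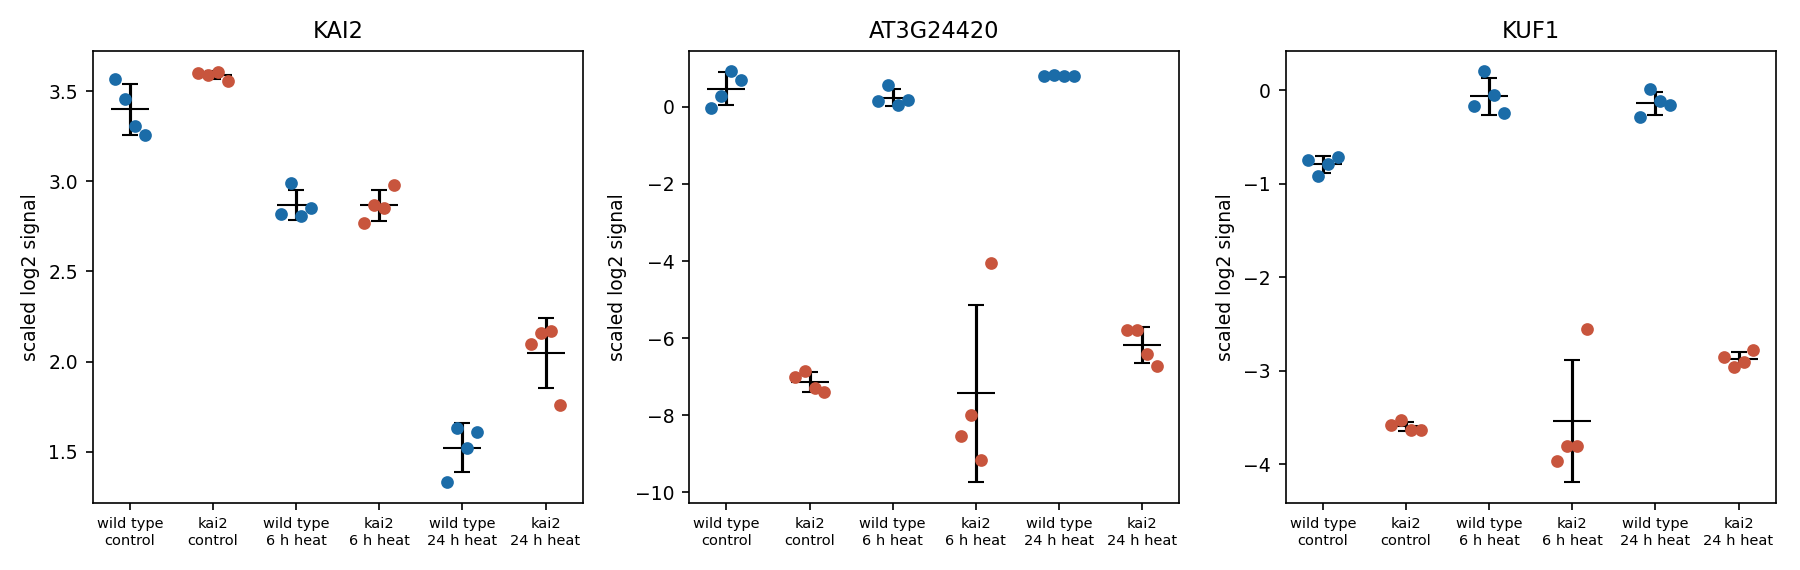
Log2 level relative to the array's 75th percentile (vertical axis) of KAI2, AT3G24420 and KUF1 on each of the 24 arrays, by group, with the group mean and SD. AT3G24420 and KUF1 lie lower in kai2 than in the wild type at each time, whereas the KAI2 means differ between genotypes by 0.19, 0.00 and 0.52.

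The first principal component, with 47.2% of the variance, separated the control, 6 h and 24 h arrays. On the next, with 19.3%, wild-type control array 1 lay at 42.65, near the kai2 control arrays at 48.84 to 55.61 and apart from wild-type control arrays 3 and 4 at -22.91 and -29.87. Arrays of a group correlated with r of 0.9506 to 0.9973 across genes. The wild-type control arrays lay furthest apart, with r of 0.951 to 0.995 and a median SD per gene of 0.171, against 0.063 in the kai2 control. Between wild-type control arrays 4 and 1, 2990 genes differed at least 2-fold, against 301 between kai2 control arrays 4 and 1. The mean of the immune list on wild-type control arrays 1 to 4 was -0.77, 1.38, 1.97 and 2.46, that of the senescence list -1.15, -0.60, 1.53 and 1.53, and that of the auxin list -1.10, -1.38, -1.73 and -2.04. Every comparison that uses the wild-type control rests on these arrays. The fit pools the spread of each gene over all 24 arrays, so standard errors and p-values of these comparisons tend to understate it. Comparisons without the wild-type control are charged with a part of it.

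**Figure D2:**
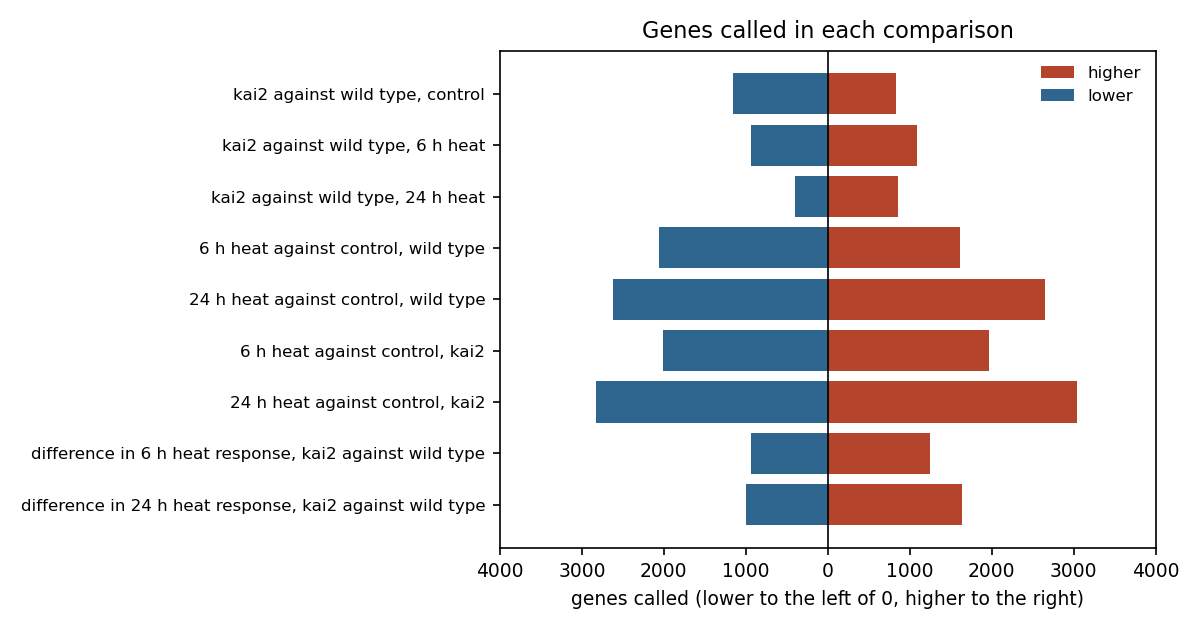
Number of genes (horizontal axis) called higher and lower in each of the 9 comparisons (vertical axis), at an adjusted p under 0.05 and a change of at least 2-fold. Counts range from 1257 genes for kai2 against the wild type after 24 h of heat to 5862 for 24 h of heat against the control in kai2.

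The first question was how wild-type seedlings responded to 6 h of heat. Small heat shock proteins, which hold unfolding proteins in a soluble state, were among the genes that rose most. AT1G53540 (HSP17.6C) rose by a log2 change of 10.55 ± 0.48, AT2G29500 (HSP17.6B) by 8.21 ± 0.10 and HSP18.2 by 7.66 ± 0.18, while the mitochondrial HSP23.6-MITO rose by 11.52 ± 0.29 from a control in which 2 of 4 arrays were well above background. Hop3, a co-chaperone, rose by 6.53 ± 0.17 (highest adjusted p of these, 1.45e-13). Of the 30 heat shock proteins and co-chaperones, 25 rose and 0 fell, with a median change of 5.21 (camera adjusted p = 3.37e-14, and adjusted p = 0.386 with an estimated correlation). Of the 23 heat shock factors and regulators, 6 rose and 1, HSFA6A, fell (camera adjusted p = 0.147). HSFA2, a factor that prolongs the heat response, rose by 4.76 ± 0.28 (adjusted p = 5.55e-12) and the coactivator MBF1C by 3.28 ± 0.39 (adjusted p = 2.47e-07). KAI2 was lower by -0.53 ± 0.09, under 2-fold (adjusted p = 1.35e-05).

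Most genes of warm-temperature growth rose in the wild type at 6 h, and a part of the cell cycle, anthocyanin and immune genes fell. In the auxin and warm-growth list, 15 of 21 rose and 1, EXPA10, fell (median 1.37, camera adjusted p = 0.00291, and adjusted p = 0.872 with an estimated correlation), and without wild-type control arrays 3 and 4 10 rose. The auxin synthesis gene YUC8 rose by 3.40 ± 0.16 and the growth gene SAUR19 by 2.78 ± 0.40 (highest adjusted p = 3.24e-06), and YUC9 rose by 5.32 ± 0.39 from a control with 1 of 4 arrays well above background (adjusted p = 2.13e-10). Of 19 cell cycle and replication genes 11 fell and 0 rose (median -1.21, camera adjusted p = 6.95e-05, and adjusted p = 0.872 with an estimated correlation). In the same comparison 8 of 13 root markers fell (median -1.58, camera adjusted p = 0.119), and the labels do not settle whether the samples held roots. The ribonucleotide reductase genes TSO2 and RNR1 fell, with changes of -1.91 ± 0.14 and -1.65 ± 0.10, and the sliding clamp gene PCNA1 fell by 1.42 ± 0.14 (highest adjusted p = 1.06e-08). Of 26 phenylpropanoid and anthocyanin genes 11 fell (camera adjusted p = 0.00105, and adjusted p = 0.872 with an estimated correlation), among them DFR at least 85.7-fold, AT5MAT at least 26.3-fold and LDOX at least 24.1-fold (highest adjusted p = 1.26e-12). The list's call was lost with a filter that asked for signal on all 24 arrays (adjusted p = 0.0671).

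Of the 13 immune genes 8 fell and 0 rose (camera adjusted p = 0.0215, and adjusted p = 0.872 with an estimated correlation), on a control whose list means ran from -0.77 to 2.46. PR5, a pathogenesis-related protein, fell by 4.0 ± 0.35 and EDS5, a transporter needed for salicylic acid, fell by 2.96 ± 0.30 (highest adjusted p = 2.75e-08). Without wild-type control arrays 3 and 4, chosen after seeing the data, the adjusted p of this list was 0.151, and without array 4 alone it was 0.0516. Of 14 genes of the unfolded protein response, CNX1, CRT1a, ATERDJ3A and ATERDJ3B rose and BIP3 fell (camera adjusted p = 0.0276, adjusted p = 0.872 with an estimated correlation, 0.101 in the authors' values, 0.155 without control arrays 1 and 2, and 0.0781 without array 1 alone). BIP3 changed by -0.82 without control arrays 3 and 4 and ATERDJ3B by 0.78 without arrays 1 and 2, so both calls were lost there. APX2, an ascorbate peroxidase, rose by 8.37 ± 0.36 from a control with 1 of 4 arrays well above background, and the glutathione transferase gene GSTU24 fell by 4.32 ± 0.28, in a list of 30 scavenging genes of which 1 rose and 3 fell (camera adjusted p = 0.903). Of 30 abscisic acid genes RAB18 and ABF3 rose and 5 fell, among them COR15A with a change of -3.25 ± 0.33 and LTI78 (RD29A) with -2.33 ± 0.25. The cold-regulated gene COR15B changed by -5.01 ± 0.20, the clock gene RVE2 by -3.59 ± 0.09 and PCC1 by -5.99 ± 0.38. Clock genes also vary with the time of day, and the time at which controls were harvested is not given in the sources used here, so heat and the time of day are not separated for these genes. GolS1, which makes the raffinose precursor galactinol, rose by 4.46 ± 0.31, and the defensin gene PDF1.2 fell by 5.14 ± 0.85 (highest adjusted p of this group, 1.73e-05). In the senescence list 1 of 16 genes, SAG21, fell, and 0 did when adjusted over the list alone, whereas without wild-type control arrays 3 and 4 8 rose and 0 fell. In all, 3668 genes were called, of which 1613 rose and 2055 fell. Of those that fell, 342 were well above background on no 6 h array, and of those that rose, 125 on no control array. With no filter on dim genes 3799 rose and 2128 fell, and with normexp and quantile normalization 1007 rose and 1140 fell. The control and the 6 h arrays lay on different slides and scan days.

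After 24 h of heat, most heat shock protein genes were higher in the wild type than in the control and most immune genes lower. AT1G53540 was higher than in the control by 8.43 ± 0.48, AT2G29500 by 6.75 ± 0.10 and HSP23.6-MITO by 10.05 ± 0.29 (highest adjusted p = 2.11e-12). Of 30 heat shock proteins 24 rose and 1, Hsp70-2, fell (median 2.93, camera adjusted p = 3.66e-07, and adjusted p = 0.803 with an estimated correlation). The ER chaperone gene BIP3 fell at least 101.0-fold (adjusted p = 7.62e-09). Of 13 immune genes 12 fell (median -4.15, camera adjusted p = 3.98e-04, and adjusted p = 0.803 with an estimated correlation), on the control whose list means ran from -0.77 to 2.46. The regulator WRKY38 changed by -5.42 ± 0.61, the glucanase gene BGL2 (PR2) by -4.90 ± 0.84 and PR5 by -4.90 ± 0.35 (highest adjusted p = 2.35e-05). Outside the list, the defensin genes PDF1.2 and PDF1.3 changed by -8.60 ± 0.85 and -6.87 ± 0.60, and the glucanase gene BG3 by -6.98 ± 0.46 (highest adjusted p = 1.17e-08), with PDF1.2 well above background on 2 of 4 heated arrays.

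Most genes of the phenylpropanoid, flavonoid and anthocyanin list were higher in the wild type at 24 h than in the control. Of 26 members 18 rose and 1 fell (camera adjusted p = 0.00176, and adjusted p = 0.803 with an estimated correlation), a call lost in the authors' values (adjusted p = 0.356). TT4, chalcone synthase, rose by 3.16 ± 0.08 and the anthocyanin glycosyltransferase gene UF3GT by 2.92 ± 0.21, and the repressor MYBL2 fell by 3.65 ± 0.13 (highest adjusted p = 1.15e-10). In the auxin list 12 rose, or 6 without wild-type control arrays 3 and 4, and PIF4 and TCH4 fell (camera adjusted p = 0.0697), with YUC9 higher by 6.35 ± 0.39 and SAUR19 by 3.41 ± 0.40 (highest adjusted p = 1.61e-07). Among 30 abscisic acid genes, 4 rose and 5 fell, or 4 adjusted over the list alone, and LTI78, COR15A and KIN2 changed by -4.15 ± 0.25, -3.97 ± 0.33 and -3.11 ± 0.19 (highest adjusted p = 1.09e-09). The light-harvesting genes LHCB2.1 and CAB2 changed by -2.03 ± 0.26 and -1.32 ± 0.12 (higher adjusted p of the pair = 6.13e-07), with LHCB2.2 the other of 28 photosynthesis genes to fall (camera adjusted p = 0.0697), at -0.90 without wild-type control arrays 1 and 2.

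Among 30 genes that scavenge reactive oxygen species 3 rose and 7 fell at 24 h (camera adjusted p = 0.379). APX2 was higher by 8.10 ± 0.36, with 1 of 4 control arrays well above background, the catalase gene CAT2 by 1.71 ± 0.08, and DHAR2 was the other to rise (highest adjusted p for the pair with values, 1.58e-13). SEN1, a marker of darkness and senescence, fell by 4.24 ± 0.23 (adjusted p = 1.50e-12), and SAG29, a sugar transporter of senescing leaves, rose by 4.58 ± 0.80 from a control with 2 of 4 arrays well above background (adjusted p = 3.08e-05). In this list 1 rose and 7 fell (camera adjusted p = 0.0644). The clock gene RVE8 was higher than in the control by 2.82 ± 0.30 (adjusted p = 3.23e-08), with 3 of 4 control arrays well above background, and the time of day may differ here too. SESA3, a seed storage albumin, rose at least 21.1-fold (adjusted p = 2.39e-12). KAI2 fell by 1.88 ± 0.09 (adjusted p = 7.80e-14). In all, 5277 genes were called, 2652 higher and 2625 lower, between arrays of different slides and scan days.

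In kai2, most heat shock protein genes rose at 6 h of heat. AT1G53540 rose by 11.52 ± 0.48 and HSP18.2 by 9.61 ± 0.18, and the chloroplast protein gene HSP21 and the ER protein gene ATHSP22.0 rose at least 10536-fold and at least 7707.2-fold (highest adjusted p = 4.45e-14). Of 30 heat shock proteins 19 rose and 1, Hsp70-2, fell (median 3.84, camera adjusted p = 1.93e-07, and adjusted p = 0.82 with an estimated correlation). HSFA2 rose by 2.72 ± 0.28, whereas HSFA7A fell by 3.22 ± 0.15 (highest adjusted p = 2.47e-08). In the unfolded protein response list ATERDJ3A, ATERDJ3B and SARA1A rose and BIP3 fell (camera adjusted p = 0.0278, and adjusted p = 0.921 with an estimated correlation), and BIP3 changed by -0.57 with normexp correction. KAI2 was lower by -0.72 ± 0.09, under 2-fold (adjusted p = 2.41e-07).

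A part of the abscisic acid and glucosinolate genes and most jasmonate genes rose in kai2 at 6 h. Of 30 abscisic acid genes 13 rose and 0 fell (camera adjusted p = 0.00386, adjusted p = 0.921 with an estimated correlation, and 0.139 in the authors' values). The phosphatase gene HAI1 rose by 4.21 ± 0.73 and the factor gene ABF3 by 2.58 ± 0.15 (highest adjusted p = 3.33e-05). Of 17 jasmonate genes 10 rose, and PDF1.2 and PDF1.2b fell (camera adjusted p = 0.0173, adjusted p = 0.921 with an estimated correlation, and 0.335 in the authors' values). VSP1 and VSP2, storage proteins induced by jasmonate, rose by 2.88 ± 0.34 and 2.85 ± 0.32, and PDF1.2 fell by 5.51 ± 0.85 (highest adjusted p = 7.14e-06). Of 19 glucosinolate genes 8 rose and 1, MYB51, fell (camera adjusted p = 1.48e-04, and adjusted p = 0.82 with an estimated correlation). MYB34, a regulator of indole glucosinolates, rose by 3.07 ± 0.13, the sulfotransferase gene SOT17 by 1.63 ± 0.12 and the glucosyltransferase gene UGT74B1 by 1.48 ± 0.05 (highest adjusted p = 1.37e-10).

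Of 19 cell cycle genes 8 fell and 0 rose in kai2 at 6 h (camera adjusted p = 0.00315, and adjusted p = 0.921 with an estimated correlation), and 7 of 13 root markers fell (median -1.10, camera adjusted p = 0.354). TSO2 and RNR1 changed by -1.48 ± 0.14 and -1.31 ± 0.10 (highest adjusted p = 1.45e-08). In the wax list 6 of 28 rose and 4 fell, with the elongase gene KCS2 higher by 4.06 ± 0.20 and the wax ester synthase gene WSD1 by 3.01 ± 0.18, and the lipid transfer protein gene LTP4 rose by 7.26 ± 0.63 (highest adjusted p = 2.53e-09). In the phenylpropanoid list 3 rose and 9 fell: PAP1, an activator of anthocyanin synthesis, rose by 3.60 ± 0.18, and DFR fell by 3.33 ± 0.29 (highest adjusted p = 2.62e-09). In the auxin list 6 rose and 5 fell, with SAUR15 lower by -3.52 ± 0.39 (adjusted p = 9.17e-08). GolS1 and GolS2 rose by 3.48 ± 0.31 and 3.62 ± 0.23, and PCC1 fell by 6.55 ± 0.38 (highest adjusted p = 3.95e-09). In all, 3973 genes were called, 1963 higher and 2010 lower, between arrays of different slides and scan days. With no filter on dim genes 3417 were higher and 2066 lower, and with normexp and quantile normalization 1212 and 1224.

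After 24 h, kai2 had 22 of 30 heat shock protein genes higher than in its control and 1, Hsp70-2, lower (median 3.18, camera adjusted p = 4.29e-06, and adjusted p = 0.965 with an estimated correlation). AT1G53540 was higher by 10.97 ± 0.48 and ATHSP22.0 at least 482.0-fold (highest adjusted p = 3.02e-14). HSFA3 rose by 2.75 ± 0.06 and HSFA7A fell by 3.40 ± 0.15 (highest adjusted p = 2.52e-14). Among 28 photosynthesis genes 9 were lower and 0 higher (camera adjusted p = 1.19e-04, and adjusted p = 0.965 with an estimated correlation), with LHCB2.1 lower by -3.45 ± 0.26, LHCB2.2 by -2.01 ± 0.20 and CAB2 by -1.98 ± 0.12 (highest adjusted p = 1.50e-08). Of 26 phenylpropanoid genes 16 rose, and GL3 and MYBL2 fell (camera adjusted p = 0.00508, adjusted p = 0.965 with an estimated correlation, and 0.465 in the authors' values), with GL3 at -0.37 with normexp correction. TT4 rose by 3.31 ± 0.08 and MYBL2 fell by 5.06 ± 0.13 (highest adjusted p = 1.75e-17).

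Among 30 abscisic acid genes, 14 rose and 4 fell in kai2 at 24 h (camera adjusted p = 0.211). NCED5, of abscisic acid synthesis, rose by 5.08 ± 0.20 and HAI1 by 5.14 ± 0.73 (highest adjusted p = 2.29e-06). Of 13 immune genes 7 fell (camera adjusted p = 0.211), with BGL2 lower by -4.25 ± 0.84 (adjusted p = 1.12e-04), and PDF1.2 fell by 8.50 ± 0.85 with 2 of 4 heated arrays well above background (adjusted p = 1.30e-08). WSD1 rose by 3.79 ± 0.18, LTP4 by 6.90 ± 0.63 and the clock gene RVE8, for which the time of day may differ, by 3.27 ± 0.30 (highest adjusted p = 3.48e-09). In the senescence list 1 rose and 6 fell (camera adjusted p = 0.211): SAG29 rose by 4.81 ± 0.80, SEN1 fell by 5.96 ± 0.23 and the asparagine synthetase gene ASN1 fell by 4.73 ± 0.72 (highest adjusted p = 1.66e-05). GolS2 rose by 4.38 ± 0.23 and GolS1 by 2.66 ± 0.31 (highest adjusted p = 1.39e-07). The seed genes SESA3 and EM1 rose at least 18.7-fold and at least 11.3-fold (highest adjusted p = 1.03e-09), and EM1 changed by 0.91, under 2-fold, with normexp background correction. KAI2 fell by 1.54 ± 0.09 (adjusted p = 1.43e-12). In all, 5862 genes were called, 3035 higher and 2827 lower, between arrays of different slides and scan days.

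**Figure D3:**
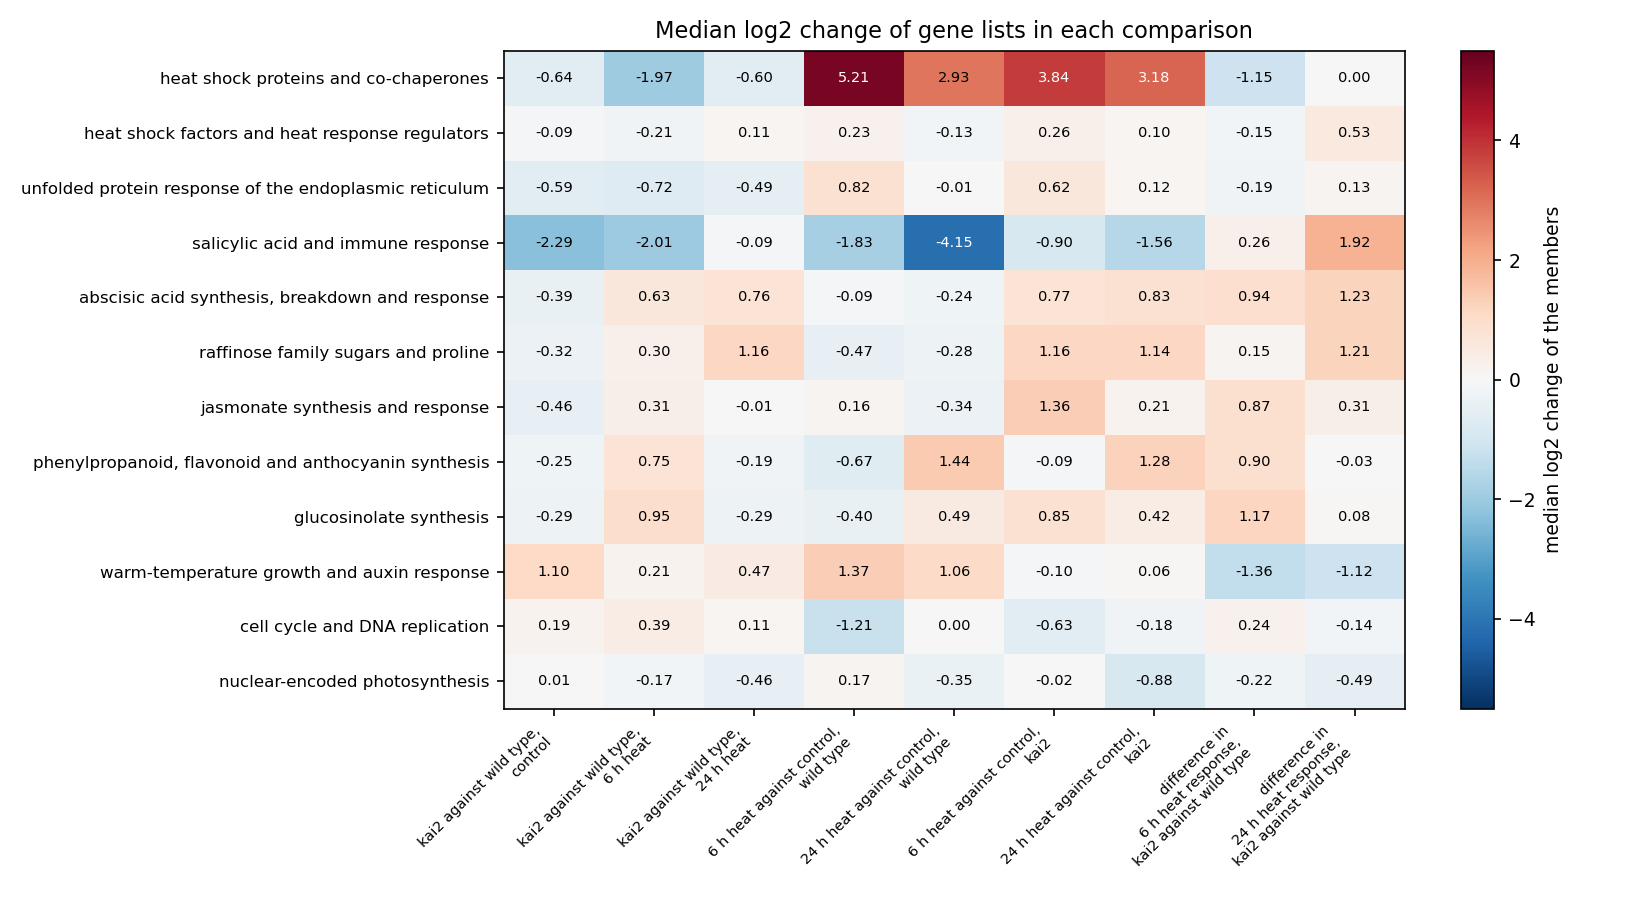
Median log2 change (colour) of the measured members of 12 gene lists (vertical axis) in each of the 9 comparisons (horizontal axis), with the median printed in each cell. Heat shock proteins have medians of 5.21 and 3.84 at 6 h in the wild type and kai2 and of -1.97 in kai2 against the wild type at 6 h.

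The comparison of the genotypes at 23 °C asked what the mutation changed before any heat. Most immune genes were lower and most auxin and warm-growth genes higher in kai2. Of 13 immune genes 10 were lower and 0 higher (median -2.29, camera adjusted p = 4.29e-06, and adjusted p = 0.558 with an estimated correlation). PR5 was lower by -4.36 ± 0.35, BGL2 by -3.73 ± 0.84, WRKY38 by -3.38 ± 0.61 and PBS3, an enzyme of salicylic acid synthesis, by -3.24 ± 0.81 (highest adjusted p = 0.00227). The 4 kai2 arrays had list means of -1.44 to -0.99, below each of the wild-type arrays at -0.77 to 2.46. Without wild-type control arrays 3 and 4, a choice made after seeing the data, 8 were lower and 0 higher (camera adjusted p = 1.59e-04), and PBS3 was no longer called at -1.60. Of 21 auxin and warm-growth genes 12 were higher and 0 lower (median 1.1, camera adjusted p = 3.12e-05, and adjusted p = 0.558 with an estimated correlation). SAUR19, SAUR23, IAA6 and IAA5 were higher by 3.79 ± 0.40, 3.17 ± 0.32, 3.11 ± 0.38 and 3.04 ± 0.34 (highest adjusted p = 1.55e-06). Wild-type list means here were -2.04 to -1.10 and kai2 means -0.02 to 0.10, and without arrays 3 and 4 the counts were 13 and 0.

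**Figure D4:**
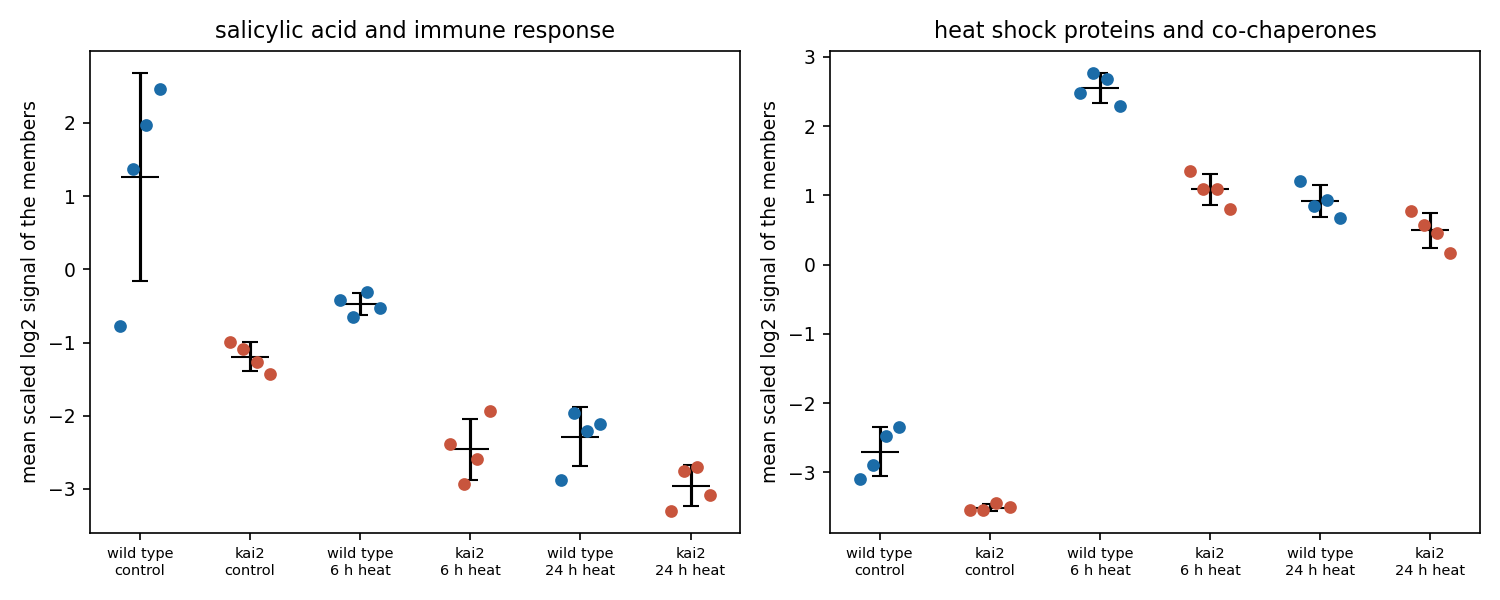
Mean level of the immune list and of the heat shock protein list on each of the 24 arrays (vertical axis, log2 relative to the array's 75th percentile), by group, with the group mean and SD. The immune means of the wild-type control arrays run from -0.77 to 2.46, and no other group reaches above -0.31.

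Some heat shock protein and abscisic acid genes were lower in kai2 at 23 °C, and most members of both lists were not called. Of 30 heat shock proteins 11 were lower and 0 higher (median -0.64, camera adjusted p = 0.00136, and adjusted p = 0.61 with an estimated correlation), with list means of -3.10 to -2.35 on the wild-type arrays and of -3.55 to -3.45 on the kai2 arrays. Without wild-type arrays 3 and 4, 5 were lower (camera adjusted p = 0.0262), and in the authors' values the list did not pass (adjusted p = 0.0596). HSP17.6A was at least 3.6-fold lower (adjusted p = 5.88e-06), with 3 of 4 wild-type arrays well above background, but differed by -0.31 with normexp correction. HSFA2 was lower by -2.72 ± 0.28 and HSFA7A higher by 1.93 ± 0.15 (highest adjusted p = 1.30e-07), in a list of 23 factors with 1 higher and 4 lower (camera adjusted p = 0.239). BIP3 was lower by -3.84 ± 0.64 (adjusted p = 4.80e-05), and with ATERDJ3A it made up the 2 of 14 unfolded protein response genes called (camera adjusted p = 6.61e-05, adjusted p = 0.61 with an estimated correlation, and 0.0672 in the authors' values). Of 30 abscisic acid genes 7 were lower and 0 higher (camera adjusted p = 0.00561, and adjusted p = 0.61 with an estimated correlation), with wild-type list means of -1.11 to -0.34 and kai2 means of -1.38 to -1.19. The list's adjusted p was 0.135 without wild-type arrays 3 and 4 and 0.0596 in the authors' values, and without arrays 1 and 2 11 were lower. The phosphatase gene HAI2 was lower by -2.62 ± 0.46 and NCED5 by -2.52 ± 0.20 (highest adjusted p = 8.99e-05), and NCED5 differed by -0.87 with normexp correction.

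In the wax list CYP96A15, a midchain alkane hydroxylase of wax synthesis, was at least 9.0-fold lower and WSD1 lower by -2.58 ± 0.18 (higher adjusted p of the pair = 6.02e-10), CER4 was higher, and with normexp correction CYP96A15 differed by -0.69 and CER4 by 0.94. Of 17 jasmonate genes 1, JAZ7, was higher by 3.3 ± 0.59 (adjusted p = 9.67e-05) and 4 were lower (camera adjusted p = 0.0419, and adjusted p = 0.617 with an estimated correlation). Without wild-type arrays 3 and 4 2 were higher and 0 lower (adjusted p = 0.398), and the list's adjusted p was 0.0513 with normexp correction, 0.872 in the authors' values and 0.052 to 0.13 on leaving out wild-type array 3 or 4 or kai2 array 1 or 2. A single member was called in the phenylpropanoid list, MYBL2, higher (camera adjusted p = 0.0441, and adjusted p = 0.61 with an estimated correlation), and in the glucosinolate list, CYP83B1, lower (camera adjusted p = 9.66e-04, adjusted p = 0.558 with an estimated correlation, and 0.0596 in the authors' values). MYBL2 differed by 0.99, under 2-fold, without wild-type arrays 1 and 2. The phenylpropanoid list's adjusted p was 0.524 without wild-type arrays 3 and 4, 0.0619 with quantile normalization, 0.076 with normexp correction, 0.171 in the authors' values and 0.0504 to 0.13 on leaving out wild-type array 2, 3 or 4 or kai2 array 1 or 2. In the senescence list 4 were higher and 3 lower (camera adjusted p = 0.93), on wild-type list means of -1.15 to 1.53. The sugar-responsive gene DIN10 was higher by 1.94 ± 0.15 (adjusted p = 4.39e-09). Among 30 scavenging genes 2, ERD9 and GSTF6, were lower, or 3 adjusted over the list alone, and ERD9 differed by -0.35 without wild-type arrays 3 and 4. Large increases included AT2G37030 at 5.07 ± 0.77, AT5G62280 at 4.52 ± 0.35 and P1R3 at 4.50 ± 0.14. Large decreases included TAT3, a tyrosine aminotransferase, at -5.39 ± 0.82, PNP-A, a plant natriuretic peptide, at -4.94 ± 0.56, the receptor kinase CRK6 at -4.72 ± 0.64 and BG3 at -4.49 ± 0.46 (highest adjusted p of these, 1.84e-05). In all, 1992 genes were called, 830 higher and 1162 lower in kai2. Without wild-type arrays 3 and 4 the split turned to 916 higher and 636 lower, and without arrays 1 and 2 it was 968 higher and 2084 lower. It was 488 higher and 803 lower with normexp and quantile normalization, and turned to 6250 higher and 5067 lower without a fold minimum.

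After 6 h of heat, kai2 had lower levels of most heat shock protein transcripts than the wild type. Of 30, 22 were lower and 3, HSP18.2, HSP21 and ATHSP22.0, were higher (median -1.97, camera adjusted p = 1.20e-09, and adjusted p = 0.33 with an estimated correlation). The disaggregase gene HSP101 was lower by -3.54 ± 0.20 and Hsp70-2 by -3.57 ± 0.38, while HSP21 was higher by 3.90 ± 0.33 (highest adjusted p = 2.38e-07). Of 23 heat shock factors and regulators 3 were higher and 5 lower (camera adjusted p = 0.00382, adjusted p = 0.394 with an estimated correlation, and 0.103 in the authors' values). HSFA2, HSFA7A, DREB2A and MBF1C were lower by -4.76 ± 0.28, -3.47 ± 0.15, -2.69 ± 0.41 and -2.61 ± 0.39 (highest adjusted p = 1.66e-05). In the unfolded protein response list 4 of 14 were lower and 1, SARA1A, higher (camera adjusted p = 1.94e-05, adjusted p = 0.485 with an estimated correlation, and 0.103 in the authors' values), with SARA1A at 0.99 with normexp correction. BIP3 was lower by -3.90 ± 0.64 (adjusted p = 3.95e-05), with 2 of 4 kai2 arrays well above background.

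A part of the glucosinolate, anthocyanin and abscisic acid genes were higher in kai2 at 6 h, and most immune genes lower. Of 19 glucosinolate genes 9 were higher and 1 lower (camera adjusted p = 1.97e-08, and adjusted p = 0.287 with an estimated correlation). FMO GS-OX1 and CYP79F1, of aliphatic glucosinolate synthesis, and SOT17 were higher by 1.52 ± 0.11, 1.51 ± 0.11 and 1.24 ± 0.12, and MYB51 was lower by -1.21 ± 0.21 (highest adjusted p = 7.91e-05) but by -0.98 with normexp correction. Of 26 phenylpropanoid genes 11 were higher and 0 lower (camera adjusted p = 1.19e-04, adjusted p = 0.35 with an estimated correlation, 0.364 in the authors' values, and 0.099 with signal on all 24 arrays). PAP1 was higher by 3.22 ± 0.18, DFR at least 10.2-fold and AT5MAT at least 5.0-fold (highest adjusted p = 4.66e-09), while with normexp correction DFR differed by 0.99 and AT5MAT by 0.46. Among 30 abscisic acid genes, 6 were higher and 1, CYP707A3, lower (camera adjusted p = 0.00382, adjusted p = 0.551 with an estimated correlation, and 0.0635 in the authors' values). The factor gene ABI5, COR15A and LTI78 were higher by 2.25 ± 0.19, 2.19 ± 0.33 and 2.01 ± 0.25 (highest adjusted p = 1.88e-05). Of 13 immune genes 7 were lower and 0 higher (median -2.01, camera adjusted p = 4.40e-04, and adjusted p = 0.551 with an estimated correlation). BGL2, WRKY38 and PBS3 were lower by -4.09 ± 0.84, -3.70 ± 0.61 and -3.49 ± 0.81, and outside the list SARD1, a regulator of salicylic acid synthesis, by -4.95 ± 0.54 (highest adjusted p = 0.00127).

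Of 17 jasmonate genes 4 were higher in kai2 at 6 h and 0 lower (camera adjusted p = 0.0348, adjusted p = 0.651 with an estimated correlation, 0.404 in the authors' values, 0.091 without wild-type array 2, and 0.0567 without kai2 array 3), with VSP2 and VSP1 higher by 2.67 ± 0.32 and 2.62 ± 0.34 (highest adjusted p = 2.53e-06). Of 28 wax genes 3 were higher and 1, CYP96A15, at least 24.5-fold lower (adjusted p = 1.29e-11; camera adjusted p = 0.0348, adjusted p = 0.651 with an estimated correlation, 0.0555 in the authors' values, 0.0635 with only the groups compared in the fit, and 0.0504 to 0.0636 on leaving out wild-type array 1 or 3 or kai2 array 4). In the cell cycle list 3 of 19, all B1-type cyclins, were higher, CYCB1;1 by 1.36 ± 0.19 (adjusted p = 5.60e-06; camera adjusted p = 0.00382, adjusted p = 0.651 with an estimated correlation, and 0.206 in the authors' values), and 5 of 13 root markers were higher (camera adjusted p = 0.0888). No photosynthesis gene was called, with 0 of 28 (camera adjusted p = 0.0188, and adjusted p = 0.838 with an estimated correlation), and the list's direction turned with quantile normalization (adjusted p = 0.616), and its call was lost with normexp correction (0.538) and without wild-type array 2 (0.0745) or kai2 array 2 (0.0881). Outside these lists, TSPO, a stress-induced membrane protein, was higher by 3.64 ± 0.65, the fatty acyl reductase gene FAR8 by 3.59 ± 0.27 and the proline synthesis gene P5CS1 by 2.60 ± 0.15, and HK3, a cytokinin receptor, was lower by -5.05 ± 0.23 (highest adjusted p = 1.11e-04). In the senescence list 1 was higher and 5 lower. In all, 2028 genes were called, 1094 higher and 934 lower. The split turned to 479 higher and 615 lower with normexp and quantile normalization and to 215 higher and 288 lower in the authors' values. Both groups were scanned on the same day and lay on different slides.

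After 24 h of heat, some abscisic acid and auxin genes and the galactinol synthase genes GolS2 and GolS3 were higher in kai2 than in the wild type. Of 30 abscisic acid genes 10 were higher and 0 lower (camera adjusted p = 2.48e-05, and adjusted p = 0.733 with an estimated correlation). LTI78 was higher by 3.18 ± 0.25, HAI1 by 2.97 ± 0.73, and NCED9, of abscisic acid synthesis, at least 13.1-fold (highest adjusted p = 0.00265), although NCED9 differed by 0.99 with normexp correction. Array 4 of kai2 stood apart in the abscisic acid list mean (-0.60, others -0.13 to -0.11), in LTI78 (1.41, others 2.57 to 2.71) and in HAI1 (1.02, others 2.12 to 2.23). Of 21 auxin and warm-growth genes 8 were higher and 0 lower (camera adjusted p = 0.0349, and adjusted p = 0.737 with an estimated correlation), a call lost without kai2 array 2 (adjusted p = 0.0556). IAA6, IAA19 and YUC8 were higher by 2.62 ± 0.38, 1.86 ± 0.17 and 1.68 ± 0.16 (highest adjusted p = 2.07e-05). GolS2, GolS3 and P5CS1 were higher by 2.34 ± 0.23, 1.62 ± 0.28 and 1.52 ± 0.15 (highest adjusted p = 1.34e-04), in a list of 9 genes of raffinose and proline with 5 higher and 2 lower (camera adjusted p = 0.0622), and GolS3 differed by 0.71 with normexp correction.

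The heat shock proteins at 24 h included 9 lower and 2 higher in kai2 (median -0.60, camera adjusted p = 0.0169, adjusted p = 0.737 with an estimated correlation, and 0.0709 in the authors' values). HSP18.2 and HSP21 were higher by 3.06 ± 0.18 and 2.16 ± 0.33, and Hsp70-2 was lower by -2.11 ± 0.38 (highest adjusted p = 1.70e-04). HSFA6B was higher by 2.65 ± 0.36 and HSFA2 lower by -1.48 ± 0.28 (highest adjusted p = 2.38e-04), with HSFC1 the other of 23 factors called (camera adjusted p = 0.383). Of 28 photosynthesis genes 1, LHCB4.2, was lower by -1.06 ± 0.23 (adjusted p = 8.48e-04; camera adjusted p = 6.62e-07, and adjusted p = 0.737 with an estimated correlation). LHCB4.2 lay under 2-fold at -0.94 with quantile normalization, at -0.89 with normexp correction, at -0.82 with array weights and at -0.79 without kai2 array 4. In the phenylpropanoid list 1, MYB90, was higher and 4 lower (camera adjusted p = 0.0252, adjusted p = 0.737 with an estimated correlation, 0.158 in the authors' values, and 0.0561 with signal on all 24 arrays). No glucosinolate gene was called, with 0 of 19 (camera adjusted p = 0.00529, adjusted p = 0.737 with an estimated correlation, and 0.0832 in the authors' values). BIP3 was higher and ATERDJ3A lower in the unfolded protein response list (camera adjusted p = 0.0298, adjusted p = 0.774 with an estimated correlation, 0.0585 with quantile normalization, 0.0629 with normexp correction, 0.646 in the authors' values, and 0.0515 without kai2 array 4). With normexp correction BIP3 differed by 0.18, ATERDJ3A by -0.91 and MYB90 by 0.32, all under 2-fold, and without kai2 array 4 ATERDJ3A differed by -0.77.

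Of 13 immune genes 3 were lower at 24 h (camera adjusted p = 0.607), BGL2 by -3.09 ± 0.84 and PR5 by -1.59 ± 0.35 (higher adjusted p of the pair = 0.00522), with WRKY70 the other, at -0.69 without kai2 array 4. Among scavenging genes 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone, with GSTU25 higher by 3.14 ± 0.51 (adjusted p = 6.30e-05). In the senescence list 2 were higher and 2 lower, or 3 and 3 adjusted over the list alone. CYP96A15 was at least 18.5-fold lower (adjusted p = 2.95e-10), but differed by -0.91 with normexp correction. Large decreases included AT1G30250 at -7.62 ± 0.83 and HK3 at -4.76 ± 0.23. TSPO was higher by 4.19 ± 0.65 and EDL3, an F-box gene of abscisic acid signalling, by 3.37 ± 0.64 (highest adjusted p of these, 2.93e-04). The root-expressed aquaporin gene TIP2;3 was higher by 2.96 ± 0.69 (adjusted p = 0.00177). In all, 1257 genes were called, 858 higher and 399 lower, or 429 and 195 with normexp and quantile normalization. Both groups were scanned on the same day and lay on different slides.

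The difference between the genotypes' responses to 6 h of heat asked which genes responded unequally. A higher response here is a more positive change in kai2 than in the wild type, which for a gene that fell in the wild type can be a smaller fall. Most heat shock protein genes had a lower response in kai2: 17 of 30 were lower and 3, HSP18.2, HSP21 and ATHSP22.0, a higher one (median -1.15, camera adjusted p = 3.37e-04, adjusted p = 0.712 with an estimated correlation, and 0.0801 without wild-type control arrays 1 and 2). The differences were -2.87 ± 0.29 for HSP101 and -3.58 ± 0.20 for Hsp70b. Among 23 factors 2 had a higher and 4 a lower response, or 3 and 4 adjusted over the list alone, with HSFA7A at -5.40 ± 0.21 and HSFA2 at -2.04 ± 0.39 (highest adjusted p of these, 2.81e-04). Of 19 glucosinolate genes 14 had a higher response in kai2 and 0 a lower one (median 1.17, camera adjusted p = 1.29e-11, and adjusted p = 0.0887 with an estimated correlation), SOT17 by 2.06 ± 0.16 and CYP79F1 by 1.77 ± 0.16 (highest adjusted p = 4.76e-08). In the list of 30 abscisic acid genes, 14 responded higher and 0 lower (median 0.94, camera adjusted p = 1.20e-05, and adjusted p = 0.397 with an estimated correlation). LTI78 differed by 3.71 ± 0.35, COR15A by 3.22 ± 0.47 and HAI1 by 3.20 ± 1.04 (highest adjusted p = 0.0164), and HAI1 was not called at 1.19 without wild-type control arrays 3 and 4.

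Of 26 phenylpropanoid genes 13 responded higher in kai2 at 6 h and 1, MYBL2, lower (median 0.90, camera adjusted p = 5.95e-07, adjusted p = 0.234 with an estimated correlation, and 0.0921 in the authors' values), with PAP1 at 3.38 ± 0.26 (adjusted p = 6.94e-09). Of 21 auxin genes 12 responded lower and 1, EXPA10, higher (median -1.36, camera adjusted p = 1.87e-04, and adjusted p = 0.397 with an estimated correlation), with SAUR19 at -4.22 ± 0.57 and SAUR15 at -3.94 ± 0.55 (highest adjusted p = 1.05e-05). Of 17 jasmonate genes 8 responded higher and 1, JAZ7, lower (median 0.87, camera adjusted p = 0.0027, adjusted p = 0.712 with an estimated correlation, and 0.708 in the authors' values), with the cystine lyase gene CORI3 at 3.73 ± 0.27 and VSP2 at 2.66 ± 0.46 (higher adjusted p of the pair = 1.02e-04), and JAZ7 was not called at -1.89 without wild-type control arrays 1 and 2. Of 28 wax genes 5 responded higher and 1, CER4, lower (median 0.47, camera adjusted p = 0.00994, adjusted p = 0.747 with an estimated correlation, and 0.119 without wild-type control arrays 1 and 2), and CER4 differed by -0.87 with normexp correction. TSPO differed by 6.44 ± 0.92 and P5CS1 by 2.29 ± 0.21 (highest adjusted p = 1.36e-05). In all, 2176 genes were called, 1245 with a higher and 931 with a lower response in kai2, or 783 and 645 with normexp and quantile normalization. The difference uses the wild-type control arrays, with their spread, and 4 slides.

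At 24 h of heat, most abscisic acid genes had a higher change in kai2 than in the wild type and most auxin genes a lower one. Of 30 abscisic acid genes, 19 responded higher in kai2 and 1, CYP707A1, lower (median 1.23, camera adjusted p = 3.67e-06, and adjusted p = 0.834 with an estimated correlation), with LTI78, which fell in the wild type, at 4.88 ± 0.35 and HAI1 at 4.36 ± 1.04 (highest adjusted p = 0.0017). Of 13 immune genes 8 had a higher difference, that is a smaller fall in kai2, and 0 a lower one (median 1.92, camera adjusted p = 8.75e-04, and adjusted p = 0.865 with an estimated correlation), on wild-type control means of -0.77 to 2.46. WRKY38 differed by 3.86 ± 0.87 and PR5 by 2.77 ± 0.49 (highest adjusted p = 0.00108). Of 21 auxin genes 12 responded lower and 1, EXPA10, higher (median -1.12, camera adjusted p = 0.0297, adjusted p = 0.865 with an estimated correlation, 0.119 in the authors' values, 0.0621 with normexp correction, and 0.053 with signal on all 24 arrays), SAUR19 by -3.42 ± 0.57 and SAUR23 by -2.76 ± 0.46 (highest adjusted p = 6.46e-05). Without wild-type control arrays 3 and 4, 4 of the auxin genes responded lower and 0 higher. Of 28 photosynthesis genes LHCB2.1 and LHCB4.2 responded lower (median -0.49, camera adjusted p = 8.75e-04, and adjusted p = 0.952 with an estimated correlation), LHCB2.1 by -1.42 ± 0.37 (adjusted p = 0.0035) but by -0.97 without wild-type control arrays 3 and 4, where LHCB4.2 differed by -0.85, so neither was called.

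Of 9 raffinose and proline genes 4 responded higher in kai2 at 24 h and 1, ERD5, lower (median 1.21, camera adjusted p = 0.0297, adjusted p = 0.834 with an estimated correlation, 0.129 with signal on all 24 arrays, and 0.0804 without wild-type control arrays 3 and 4), with GolS3 at 3.47 ± 0.40 and GolS2 at 3.09 ± 0.33 (higher adjusted p of the pair = 1.23e-06). Of 30 heat shock proteins 8 responded higher and 1, AT5G37670, lower (camera adjusted p = 0.764), with HSP18.2 at 2.53 ± 0.25, and HSFA7A responded lower by -2.66 ± 0.21 (highest adjusted p = 2.14e-07). TSPO differed by 6.98 ± 0.92, and FMO1, a monooxygenase of systemic acquired resistance, by 6.96 ± 1.31 (highest adjusted p = 2.22e-04). In all, 2632 genes were called, 1635 with a higher and 997 with a lower response in kai2. Without wild-type control arrays 1 and 2 the split was 2578 higher and 1477 lower, and without a fold minimum it turned to 5199 higher and 6028 lower.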

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

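The tests of probe noise and of mixing in the wild-type control, of the genes called in all 3 genotype comparisons and of wild-type RNA in kai2 array 4 at 6 h, and the fits without wild-type control arrays, were chosen only after the results they bear on had been seen.

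The heat responses of the genotypes differed, by a test of the difference itself, in 2176 genes at 6 h and 2632 at 24 h. At 6 h the median differences of the lists that passed were -1.15 for heat shock proteins, 0.47 for wax, 0.94 for abscisic acid, 0.90 for phenylpropanoids, -1.36 for auxin, 1.17 for glucosinolates and 0.87 for jasmonate. At 24 h they were 1.23 for abscisic acid, -0.49 for photosynthesis, -1.12 for auxin, 1.92 for immunity and 1.21 for raffinose and proline. Every one of these list results was lost with an estimated correlation, at adjusted p-values of 0.0887 to 0.747 at 6 h and 0.834 to 0.952 at 24 h. Single genes at 6 h differed by -5.40 (HSFA7A), -2.04 (HSFA2), -2.87 (HSP101), -3.58 (Hsp70b), 3.71 (LTI78), 3.22 (COR15A), 3.20 (HAI1), 3.38 (PAP1), 2.06 (SOT17), 1.77 (CYP79F1), -4.22 (SAUR19), -3.94 (SAUR15), 3.73 (CORI3), 2.66 (VSP2), 2.29 (P5CS1) and 6.44 (TSPO). At 24 h they differed by 4.88 (LTI78), 4.36 (HAI1), 3.86 (WRKY38), 2.77 (PR5), -3.42 (SAUR19), -2.76 (SAUR23), 3.47 (GolS3), 3.09 (GolS2), 2.53 (HSP18.2), -2.66 (HSFA7A), 6.98 (TSPO), -1.42 (LHCB2.1) and 6.96 (FMO1). Without wild-type control arrays 3 and 4, HAI1 differed by 1.19 at 6 h and LHCB2.1 by -0.97 at 24 h, so neither was called.

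Other splits of the same arrays were fitted to ask whether chance gives as many genes. For kai2 against the wild type, the real split was the 1 of 35 splits with as many genes at each time. The real counts in this fit were 1990, 2027 and 1255, and the highest of the other splits 1197, 4 and 46. The 1197 came from a split that set wild-type control array 1 with kai2 control arrays 2, 3 and 4. For heat against control the real split was again the 1 of 35 each time. Real counts were 3664 and 5268 in the wild type and 3966 and 5854 in kai2, and the highest others 911, 1905, 2 and 1. These splits cannot exclude chance, since 1 of 35 is the smallest share they can give. A split that mixes the groups also adds the group difference to the spread. Each group lay on its own slide, so a slide effect would put the real split first as well. For the difference at 6 h, 3 of 100 drawn splits gave as many as the real 2173, the highest 3015. Both other splits, with 3015 and 2545 genes, put 6 and 8 of the 8 control arrays and 0 and 2 of the 8 heated arrays in the opposite genotype. In such splits the genotype differences of both times add up in large part. For the difference at 24 h it was 1 of 100, with 2629 against a highest other of 1904. The drawn splits mix the genotypes, so genotype differences enter the spread, and the median of the other splits was 0 for both differences. They do not show how many genes equal responses would give, so they do not decide whether chance gives as many.

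Genotype differences could come from slides, since every group lay on its own slide. Slide effects as the whole cause would leave the 3 comparisons uncorrelated: across genes r was 0.44 between control and 6 h, 0.49 between 6 h and 24 h and 0.12 between control and 24 h (rho of 0.28, 0.45 and 0.03; median r 0.44), so the correlations do not decide it. For the 205 genes called in the same direction in all 3, independent lists would give 2.8. That number takes every gene as equally likely to be called, which was not tested, so the excess does not decide it either. Spike-in transcripts differed between the slides of a genotype comparison by up to 0.59 after centring, on a dim probe, and by 0.32 over the 8 brighter of 10 probes, which leaves effects on single probes open. For the 2363 genes called in 1 genotype comparison only, slide and genotype cannot be told apart. For sequence of another accession near KAI2, 4 of 709 genes within 2 Mb of the KAI2 probe were among the shared genes. The odds ratio was 0.57 (95% interval 0.15 to 1.48, Fisher's exact test p = 0.331, two-sided), so the window as a whole showed no enrichment. A segment much shorter than the window would add few genes to it, so such linked sequence stays open. For other segments, neighbours within 100 kb were counted once, which left 171 positions of the 205 shared genes. A 2 Mb window held at most 7 of these positions, against a median of 8 in 10000 random draws (permutation p = 0.994). Counting neighbours once removes a part of the clustering that a segment would give, so this count does not decide whether such segments remain. The random draws were redone after an earlier run that gave the same counts.

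The wild-type control arrays lay far apart, with the widest ranges of list means in the immune, senescence and seed marker lists. Noise of single probes is argued against by an r of 0.91 between probes of the same gene, over 6620 genes, for the difference of arrays 4 and 1. To bring the immune list mean of array 4 down to that of array 1, at least 89.4% of the RNA on array 1 would have to come from elsewhere. Heated samples as that source are argued against because the heat shock list mean lay lower on array 1 than on array 4, by -0.75, and kai2 control samples because AT3G24420 and KUF1 differed by a mean of -0.37, where that share would give -2.66. Smaller shares, other arrays and differences between the pools of plants, which may account for it, stay open as untested, and without arrays 3 and 4, 1552 genes were called between the genotypes at 23 °C, against 1992 with all.

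Array 4 of kai2 at 6 h lay nearer to the wild type than arrays 1 to 3 in genes far lower in kai2. AT1G30250, AT3G24420 and HK3 stood at -2.80, -4.05 and -3.04, against -8.91 to -8.19, -9.15 to -8.00 and -4.77 to -4.60 on the other 3. Wild-type RNA in this sample is a candidate explanation: over 21 such genes the array gained a median of 6.1% of the wild-type level over the mean of the other arrays, and it lay above the highest of them in 18, or 15 of 18 with a median of 6.4% without the 3 genes named. For RNA of the wild-type 6 h samples, the heat shock proteins lower in kai2 gave a share of -4.6%, with 0 of 15 above the mean of the other arrays. On array 1 the same share was 3.8%, with 15 of 15 above, so this measure also moves between arrays without the pattern. Wild-type RNA of another condition stays open. Without this array, 2031 genes were called between the genotypes at 6 h.

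A sample stood far from the others of its group in 2 of 24 groups of quality values, 11 of 126 of list means and 29 of 365 of printed genes, where chance gives about 1 in 20 groups. The 75th percentile of the processed signal was 2830.3 on kai2 control array 1 (others 2421.7 to 2468.5) and 2932.1 on kai2 6 h array 2 (others 2025.9 to 2098.5). Array 4 of kai2 at 24 h stood apart in the list means of heat shock factors (-1.99), scavenging genes (1.83), abscisic acid (-0.60), the cell cycle (0.28), raffinose and proline (-1.96), the clock (-1.30), autophagy (0.10) and reference genes (3.05). It also stood apart in KAI2 (1.76), Hsp70-2 (-2.13), LTI78 (1.41), TSPO (-0.90), HSFA6B (-2.50), HAI1 (1.02), EDL3 (-1.31) and LHCB4.2 (3.3). Without it, 1268 genes were called between the genotypes at 24 h. Other list means apart from their group were those of root markers on wild-type control array 4 (-4.05), reference genes on kai2 control array 1 (3.29) and the clock on wild-type 24 h array 3 (-0.54). Array 4 of kai2 at 6 h stood apart in KUF1 (-2.56), WRKY38 (-3.15), WSD1 (-3.46), HK3 (-3.04), P5CS1 (1.31) and RNR1 (0.83), and array 3 in TSPO (-1.34). In the kai2 control, array 1 stood apart in BIP3 (-5.33), P1R3 (0.17), DIN10 (4.90) and HSP18.2 (-3.24), array 2 in Hsp70b (-3.81), array 3 in FMO1 (-3.58) and array 4 in IAA5 (-0.81) and UGT74B1 (2.78). The remaining ones were WSD1 (-4.33) and BG3 (-0.25) on wild-type control array 1, HAI1 (-1.47) and EDS5 (-2.59) on wild-type 6 h array 2, GolS3 (-6.91) on wild-type 24 h array 4 and AT1G53540 (3.97) on kai2 24 h array 1.

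Probes with no gene name, which no comparison used, also responded to heat: of 3898 tested, 549 were higher and 414 lower at 6 h and 693 higher and 432 lower at 24 h in the wild type, and in kai2 491 were higher and 461 lower at 6 h and 634 higher and 650 lower at 24 h.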

How the results depend on the processing

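The fits without pairs of wild-type control arrays and those of the scanner values of the genes in the authors' table were chosen after seeing the data. Counts of genes called stayed within 1.5 times those reported with median scaling, quantile normalization, the mean of a gene's probes, only the compared groups in the fit, an intensity trend, array weights and an adjusted p of 0.01. Elsewhere the cause of a change was not tested, except where fewer genes, fewer arrays or another threshold account for it by construction. In the order used below, counts are for kai2 against the wild type at 0, 6 and 24 h, for 6 h and 24 h of heat in the wild type and then in kai2, and for the differences at 6 h and 24 h.

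With normexp background correction and quantile normalization the counts were 1291, 1094 and 624 for the genotypes, 2147 for 6 h in the wild type, 2436 for 6 h in kai2 and 1428 for the difference at 6 h. With the authors' values (9107 genes) all 9 were 617, 503, 293, 990, 1704, 1130, 1865, 650 and 829, against 982, 967, 638, 1745, 2580, 1921, 2824, 1019 and 1260 with scanner values of those genes, and the passing lists numbered 1, 3 and 3 for the genotypes, 1 each for 24 h in the wild type and kai2, and 2 for the difference at 24 h. Without a filter, 5927 genes were called for 6 h in the wild type, and 7 lists passed for 24 h in the wild type. With signal on all 24 arrays the counts were 1272 and 750 for the genotypes at 6 h and 24 h, with 5 lists for 24 h in the wild type and 3 for the difference at 24 h. Without a fold minimum the 9 counts were 11317, 11132, 9980, 15167, 16302, 15372, 16633, 9709 and 11227. With an estimated correlation 0 lists passed, where 8, 12, 9, 6, 3, 6, 3, 7 and 5 had passed. Without wild-type control arrays 3 and 4, 5 lists passed for 24 h in the wild type. Without arrays 1 and 2 the counts were 3052 for the genotypes at 23 °C and 4055 for the difference at 24 h, with 13 lists for the genotypes at 23 °C and 6 for 24 h in the wild type.

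The share of called genes that were higher moved by more than 10 percentage points for the genotypes at 6 h, from 53.9% to 43.8% with normexp and 42.7% in the authors' values, and without a filter for 6 h in the wild type (44% to 64.1%) and in kai2 (49.4% to 62.3%). Without a fold minimum it moved for the genotypes at 23 °C (41.7% to 55.2%) and 24 h (68.3% to 51.3%) and for the difference at 24 h (62.1% to 46.3%), and without wild-type control arrays 3 and 4 for the genotypes at 23 °C (to 59.0%). Directions reversed for these results. In the differences of responses, with normexp and in the authors' values, EXPA17 at 6 h was -0.11 and -0.12 (1.64 before), HSP17.6A at 24 h -0.21 and -0.18 (2.40) and YUC9 at 24 h 0.50 and 0.46 (-1.91). GSTF12 with signal on all 24 arrays was -1.06 between the genotypes at 6 h (3.46) and -0.83 in the difference at 6 h (3.53), because another of its probes was then used. The photosynthesis list between the genotypes at 6 h had an adjusted p of 0.616 with quantile normalization (0.0188), and the clock list for 6 h in the wild type 0.0239 in the authors' values (0.975). Without wild-type control arrays 1 and 2, the photosynthesis and senescence lists between the genotypes at 23 °C had adjusted p-values of 0.0475 and 0.0425 (0.93 each).

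Leaving out each replicate in turn gave counts of 1743 to 2501, 1871 to 2125, 1192 to 1268, 3456 to 3951, 5088 to 5694, 3909 to 4101, 5764 to 5898, 2027 to 2619 and 2320 to 3336. Passing lists for 24 h in the wild type ranged from 3 to 5, the higher number without wild-type control array 4. With a replicate block the counts were 1999, 2026, 1262, 3674, 5279, 3984, 5867, 2192 and 2646. The deviations of same-numbered arrays correlated with r of -0.324 to 0.394 (median 0.026), 19 of 60 pairs lay over 0.1 and 10 of 24 arrays correlated best with their own number, so the numbers were not taken to pair the samples. A slide block was not run. Among values of single genes named by the rule, normexp ended 103 calls, reversed 3 and left 609 unchanged in call, and the authors' values ended 36, reversed 3 and left 242. The unchanged values include genes called in neither fit, so they do not count calls that were kept. Signal over background limits the genes printed as bounds.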

Other observations

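The overlaps below and the genes named in them were chosen after their values were seen. A core of 205 genes differed between kai2 and the wild type in the same direction at all 3 times, 99 higher and 106 lower in kai2, where independent lists would share 1.8 and 1.0. Such lists take every gene as equally likely to be called, which was not tested. Besides AT3G24420 and KUF1 the core held HK3, a cytokinin receptor gene, lower by -3.86, -5.05 and -4.76 ± 0.23, with a further probe of the gene at -3.81, -5.05 and -4.75. WRKY54, a regulator of salicylic acid responses, was lower by -3.21, -3.95 and -2.40 ± 0.34. The heat responses of the genotypes, measured on separate arrays, shared 911 increases and 1079 decreases at 6 h (151.1 and 197.1 in independent lists) and 1933 and 1587 at 24 h (384.1 and 354.2). Opposite calls numbered 100 at 6 h and 95 at 24 h, and the log2 changes correlated across genes with r of 0.68 and 0.75, genes not being independent replicates.

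The root marker list passed in none of the heat comparisons with limma's camera. Of 13 measured, 8 fell in the wild type and 7 in kai2 at 6 h, and 6 in each at 24 h, with 0 rising (camera adjusted p = 0.119, 0.354, 0.0996 and 0.211). In kai2 against the wild type they were 2 higher at 23 °C, 5 higher at 6 h, and 4 higher and 1 lower at 24 h (camera adjusted p = 0.282, 0.0888 and 0.109). In the differences of responses 4 were higher and 1 lower at 6 h, or 2 and 0 adjusted over the list alone, and 2 higher and 1 lower at 24 h, or 1 and 1 adjusted over the list alone. Of 21 clock genes 5 were higher and 3 lower at 6 h than in the control in the wild type (camera adjusted p = 0.975), where the harvest time of the control is not given in the sources used here, and 0 differed between the genotypes at 24 h (camera adjusted p = 0.0298, adjusted p = 0.737 with an estimated correlation, 0.0709 in the authors' values, 0.0596 with only the groups compared in the fit, and 0.0923 without kai2 array 4, which stood apart in this list). Of 12 autophagy genes ATG8B rose in all 4 heat comparisons, ATG8E fell at both heat times in kai2 and had a lower response there in both differences, and ATG8F fell at 24 h in kai2. Between the genotypes 0 were called with limma. In the wild type ATG8B changed by 0.82 at 6 h and 0.99 at 24 h, under 2-fold, without control arrays 1 and 2. The 3 measured of 13 seed markers included SESA3, which rose in all 4 heat comparisons but changed by 0.75 at 6 h in the wild type without control arrays 1 and 2, and EM1, which was higher at both heat times in kai2. None of the 10 reference genes was called in any of the 9 comparisons with limma. In 22 of the 189 list tests the median, the mean and the tested direction differed in sign, and 0 of these passed.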
